A study of Mus musculus with 6 samples.

How the data were processed

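Neutrophils positive for Ly6G were sorted from blood into Ly6C-high and Ly6C-low cells, and poly(A) RNA libraries were made from 100 ng of total RNA with a strand-marking kit and 13 cycles of PCR, per the labels' protocols. They were sequenced as single-end reads of 75 cycles, per the labels' protocols. The authors quantified the reads with kallisto, which assigns reads to transcripts by shared short words and divides reads that fit several transcripts between them, and named the build GRCm39, per the submitters' processing notes. The version of kallisto, its index and whether it was run with strand are not given in the sources used here. Without known strand, reads of a gene and an overlapping antisense gene cannot be told apart.

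For each sample the deposited table gave estimated counts per transcript, TPM and the effective length of each transcript, per the file headers. The estimated counts were not whole numbers and summed to between 17192372 and 20973623 per library, and the deposited TPM summed to the same total in each library, to within rounding. Each table held 117486 transcripts. Transcripts were assigned to genes by identifier, without the version, with the GENCODE M21 annotation. That annotation is on build GRCm38, so no coordinates are given and it was used for gene names, biotypes, chromosomes and transcript sequences. Of the transcripts 99.04% matched, and they held between 99.747% and 99.767% of the estimated counts. Unmatched transcripts were left out of the library sizes and tests. Estimated counts were summed over the transcripts of each of 35853 genes and rounded to whole numbers.

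Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default settings, TMM scaling, robust dispersions and the quasi-likelihood F test with group as the term. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the genes kept. Fold changes are Ly6C-high over Ly6C-low, and CPM values are TMM-scaled. Intervals are 95% and cover the spread between the libraries, whose common biological coefficient of variation was 13.7%. PCR copies were not removed by molecular identifiers. Before the libraries were averaged they were compared by pairs: the chi-square per gene of the counts was between 14.6 and 70.7, far above sampling noise, so no library was counted as a copy of another.

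Before the data were examined, 31 gene lists were fixed, 21 on neutrophil biology and 10 of markers of other cells, and the 30 with at least 4 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Of the 30, 12 passed with the preset correlation, 0 with a correlation estimated per list and 0 with fry, whose adjusted p for change in 1 direction lay between 0.0773 and 0.399 for those 12 lists. Single genes to be named were also set beforehand. They were Ly6c1, Ly6c2 and Ly6g. They were also, in each direction, the 10 largest changes past the threshold with a mean of at least 5 CPM and groups that did not overlap, without predicted genes and pseudogenes. From each list on biology they were the 3 members with the smallest p, and from each list of other cells the 2 most abundant members. Some genes that this rule takes are not reported here. Alox15, Ear1, Mcpt8, Prss34, Cpa3 and Ccr2 were added after their values were seen. S100a8, S100a9, Cxcr2, Csf3r, Arg2, Il1b, Egr1, Lars2 and CT010467.1 are also named outside this rule. Words of 31 bases shared by the Ly6 transcripts were counted in the reference sequences.

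The alternatives tried were the replicate number as a block, DESeq2 size factors or library size alone in place of TMM, no filter, a filter on a mean count of 10, the DESeq2 1.42.0 Wald test, limma voom, length-scaled TPM in place of estimated counts, protein-coding genes alone, each library left out in turn, an estimated correlation, and fry. After the data were examined, removal of each library's trend with gene length or with GC content was added. The edgeR step was tested on simulated counts for this comparison of 11406 genes, with 200 genes changed in each of 10 runs. It called 34.48% of the genes changed 1.5-fold, 68.51% of those changed 2-fold and 93.79% of those changed 4-fold. Of its calls 7.88% were genes that had not been changed, above the nominal 5%. The rates hold for 200 changed genes per run, with every gene drawn independently of the others and no library that stood apart. Where fewer genes pass, as in the real comparison, the Benjamini-Hochberg cut-off is stricter and fewer changed genes are called. In 10 further runs every gene was again drawn independently of the others, and camera was read at an unadjusted p under 0.05. It called a list of 50 genes raised by 0.5 on the log2 scale in 10 runs and an unshifted list in 0. Members of the real lists moved together, with estimated correlations of 0.485 for interferon-stimulated and 0.593 for ribosomal protein genes. These runs therefore do not show how often camera calls an unshifted list in the real data. Tables were joined with pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.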

Results

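RNA sequencing was carried out on blood neutrophils of BALB/c mice that had carried orthotopic 4T1 tumours, a mouse mammary carcinoma line, for 4 weeks. Cells positive for Ly6G, a surface protein of mouse neutrophils, had been sorted by their surface Ly6C into a Ly6C-high and a Ly6C-low group, with 3 libraries in each. The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical. The estimated counts summed to 19781046, 19694989 and 20973623 in Ly6C-high replicates 1, 2 and 3, and to 20010700, 18969170 and 17192372 in Ly6C-low replicates 1, 2 and 3. After the filter on low counts 11406 genes were tested.

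The comparison asked how the transcripts of Ly6C-high neutrophils differed from those of Ly6C-low neutrophils in the same tumour model. Transcripts of both Ly6C genes were higher in the Ly6C-high cells, Ly6c1 by 8.38-fold and Ly6c2 by 7.46-fold. Alox15, which encodes a lipoxygenase also abundant in eosinophils, was 7.40-fold higher in the Ly6C-low cells, and Fam49a, which encodes a protein that binds the GTPase Rac1, was 1.97-fold higher there. These 4 genes, 2 in each direction, were the whole set past an adjusted p of 0.05, and 3 of them differed by 2-fold or more. The test was edgeR's quasi-likelihood test with group as the only term. With the replicate number as a block it called 61 genes, the 4 among them. Beside these single genes, whole groups of genes stood apart by small amounts. Interferon-stimulated genes and those of specific and gelatinase granules lay higher in the Ly6C-high cells, and ribosomal protein genes higher in the Ly6C-low cells. Eosinophil and basophil genes also lay higher in the Ly6C-low cells, with median log2 fold changes of -0.66 and -1.73 (-1.01 for the basophil genes without Ly6C-low replicate 3). Of 30 gene lists tested with camera 12 passed with a preset correlation and 0 with an estimated one (adjusted p = 0.53 with an estimated correlation for each of the 12).

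Ly6c1, on chromosome 15, had a normalised count, scaled by library size to CPM, of 47.9 ± 7.73 CPM in the Ly6C-high libraries and 5.72 ± 1.83 in the Ly6C-low libraries (SD, n = 3 each). Its log2 fold change was 3.07 with a standard error of 0.22, and its adjusted p was 0.00273. Ly6c2, its neighbour on chromosome 15, measured 139 ± 22.9 against 18.6 ± 5.15 CPM, a log2 fold change of 2.90 with a standard error of 0.21 and an adjusted p of 0.00381. The Ly6c1 and Ly6c2 transcripts share 581 words of 31 bases, 33.0% of those in Ly6c1 and 21.4% of those in Ly6c2, so the division of reads between the pair is uncertain. Their sum does not depend on that division: it was 187 ± 30.5 CPM in the Ly6C-high and 24.3 ± 6.97 CPM in the Ly6C-low libraries, a ratio of 7.67, with all 3 Ly6C-high libraries above all 3 Ly6C-low libraries. The two-sided exact permutation p of the sum was 0.1, the smallest that 3 against 3 libraries allow. Ly6g, the gene of the shared gate, measured 780 ± 85.6 CPM in the Ly6C-high and 553 ± 137 CPM in the Ly6C-low libraries, and its log2 fold change of 0.50 did not pass the test (adjusted p 0.278). It was 0.31 without Ly6C-low replicate 3 (adjusted p 0.220). Ly6g passed without the filter on low counts (0.00216), a setting in which single genes did not carry their own spread. Without Ly6C-low replicate 3 the adjusted p was 0.0620 for Ly6c1 and 0.0885 for Ly6c2, with log2 fold changes of 3.03 and 2.84. The adjusted p with 1 library left out ranged from 2.54e-05 to 0.0620 for Ly6c1 and from 2.29e-05 to 0.0885 for Ly6c2.

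**Figure D1:**
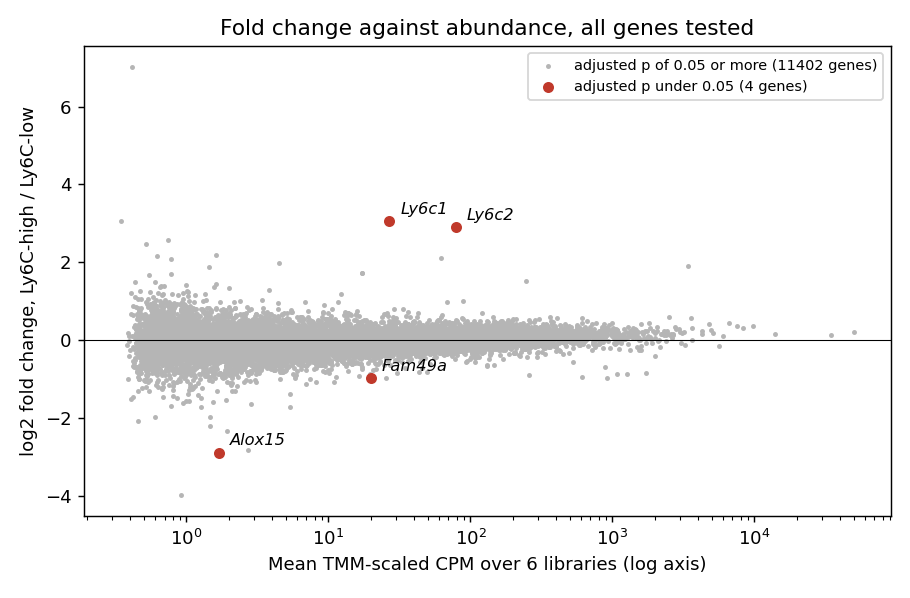
The log2 fold change (Ly6C-high over Ly6C-low, vertical axis) of each of the 11406 genes tested is plotted against its mean CPM over the 6 libraries (horizontal log axis), with the 4 genes past an adjusted p of 0.05 in red. Ly6c1 and Ly6c2 sit at 3.07 and 2.90, and Alox15 and Fam49a at -2.89 and -0.98.

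Alox15, on chromosome 11, fell by 2.89 on the log2 scale in the Ly6C-high cells, with a standard error of 0.35 and an adjusted p of 0.0132. It was a low-abundance transcript, at 0.397 ± 0.115 CPM in the Ly6C-high and 2.98 ± 0.795 CPM in the Ly6C-low libraries (SD, n = 3 each), which came from 10, 6 and 7 against 45, 73 and 54 counts. It lies under the level set for named genes and was named after its values were seen. Fam49a, on chromosome 12, fell by 0.98 on the log2 scale with a standard error of 0.14 and an adjusted p of 0.0396, from 26.5 ± 1.30 CPM in the Ly6C-low to 13.5 ± 2.55 CPM in the Ly6C-high libraries. Both calls ended when single libraries were left out, while the log2 fold changes stayed between -3.14 and -2.67 for Alox15 and between -1.14 and -0.89 for Fam49a. The adjusted p of Alox15 was 0.0625, 0.0752 and 0.110 without Ly6C-high replicates 1, 2 and 3, and 0.0819 without Ly6C-low replicate 2, in a range from 0.00779 to 0.110. That of Fam49a was 0.196 and 0.211 without Ly6C-high replicates 2 and 3, and 0.0541 and 0.123 without Ly6C-low replicates 1 and 2, in a range from 0.0160 to 0.211. The count of genes past the threshold was 22 without Ly6C-low replicate 3, 6 higher and 16 lower, and 2 without Ly6C-high replicate 2, Ly6C-high replicate 3 or Ly6C-low replicate 2. Scaling by library size alone gave 2 genes higher and 6 lower, and moved the median log2 fold change of all genes by -0.11.

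Most genes differed little between the groups. Of the 7261 genes with a mean of 5 CPM or more, 6992 (96.3%) had a 95% confidence interval that lay within a 2-fold change in either direction, and 5805 (79.9%) had one within 1.5-fold. At an unadjusted p under 0.05 there were 1626 genes, 789 higher and 837 lower in the Ly6C-high cells, where 5% of the genes tested is 570. The 2 groups did not overlap in 2410 genes (21.1%, where chance gives 10% on average). Genes move together, so such counts vary widely around their average. Other splits of the 6 libraries into 3 and 3 gave between 145 and 949 genes at an unadjusted p under 0.05. The share of genes without overlap was not computed for those splits. Without Ly6C-high replicate 2 the number at an unadjusted p under 0.05 was 993. Ly6C-low replicate 3 stood apart from the other libraries, at 38.02 on the first principal component (32.8% of the variance), where the others lay between -19.65 and 3.91.

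**Figure D2:**
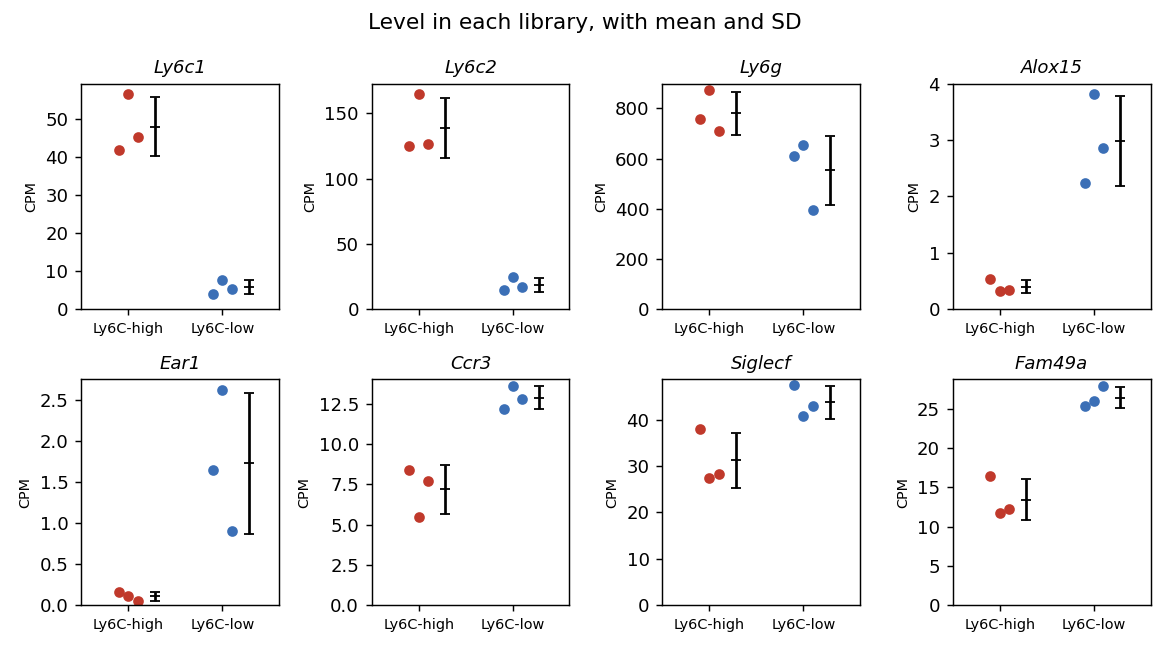
CPM in each library (points; red, Ly6C-high; blue, Ly6C-low) is shown with the group mean and SD (n = 3) for the sort markers, Fam49a and the 4 eosinophil genes Alox15, Ear1, Ccr3 and Siglecf. All 3 Ly6C-high libraries lie above all 3 Ly6C-low libraries for Ly6c1, Ly6c2 and Ly6g, and below them for the other 5 genes.

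Interferon-stimulated genes, the antiviral and signalling genes induced by type I and type II interferon, lay higher in the Ly6C-high cells. Of the 49 members tested, 48 had a log2 fold change above 0, with a median of 0.42 and quartiles of 0.23 and 0.52. Ifit2, an inhibitor of viral translation, measured 12.2 ± 0.787 against 6.52 ± 1.27 CPM, with a log2 fold change of 0.90 and a standard error of 0.16. Sp100, a nuclear body protein, had a log2 fold change of 0.52 with a standard error of 0.12 (303 ± 21.3 against 211 ± 32.1 CPM), and Ddx60, a helicase of the RNA sensing pathway, one of 0.56 with a standard error of 0.13. Adjusted over all genes tested, 0 of the 49 passed with edgeR, 6 passed with DESeq2 and 0 with voom, and 23 had an unadjusted p under 0.05. Adjusted over the list alone, 7 rose. The list as a whole passed the camera test with the preset correlation (adjusted p 1.44e-12). It did not pass otherwise (adjusted p = 0.53 with an estimated correlation), and its fry adjusted p was 0.225. The mean deviation of the list from its average over the 6 libraries was 0.45 in Ly6C-high replicate 3 and -0.39 in Ly6C-low replicate 3, and between -0.16 and 0.10 in the other libraries. The call was kept when any 1 library was left out, with an adjusted p of 6.22e-07 or less, but the median was 0.27 without Ly6C-low replicate 3.

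Genes for specific and gelatinase granule proteins and for the immature neutrophil state also lay higher in the Ly6C-high cells. Of 19 specific (secondary) granule genes 18 had a log2 fold change above 0, with a median of 0.35, as did all 12 gelatinase (tertiary) granule and secretory vesicle genes, with a median of 0.21, and 25 of 32 immature neutrophil markers, with a median of 0.29. Mmp8, the neutrophil collagenase, measured 3021 ± 61.9 against 2004 ± 327 CPM, a log2 fold change of 0.59 with a standard error of 0.13. The other specific granule genes with the smallest p were Ceacam10, at a log2 fold change of 0.48, and Anxa1, which encodes annexin A1, at 0.35. Among the gelatinase granule genes the values were 0.34 for Fpr1, a receptor for formyl peptides, 0.33 for Itgam, which encodes CD11b, and 0.31 for the metalloprotease gene Adam8. Among the immature markers Dstn, an actin-severing protein, had a value of 0.42 and Adpgk, an ADP-dependent glucokinase, one of 0.45. Kit, which is also in the basophil and mast cell list, went the other way, at -0.67 with a standard error of 0.35. The immature and the specific granule lists share 12 genes, so they are not independent of each other. Adjusted over all genes tested, 0 members of these 3 lists passed with edgeR, against 9, 4 and 13 that were higher at an unadjusted p under 0.05, and adjusted over the list alone 2, 1 and 3 rose. DESeq2 called 1, 1 and 3 members higher, and 1 immature marker lower, and voom called 0. The camera adjusted p was 4.85e-06 for specific granule genes, 0.00124 for gelatinase granule genes and 0.000153 for immature markers, and each list lost its call otherwise (adjusted p = 0.53 with an estimated correlation). Ly6C-low replicate 3 held the lowest mean deviation of the 6 libraries in all 3 lists, at -0.36, -0.23 and -0.24, and the 3 calls were kept without it and without any other 1 library. Without it the median of the specific granule genes was 0.22, and Mmp8 passed over all genes tested (log2 fold change 0.47, adjusted p 0.0235).

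Azurophil (primary) granule genes, made at the earliest stages of neutrophil formation, did not stand apart as a list, with a median of -0.09 over 12 genes and a camera adjusted p of 0.972. The members diverged: Serpinb1a, a protease inhibitor, had a log2 fold change of 0.43 and Lyz2, which encodes lysozyme, one of 0.58, against -0.17 for Gusb. Of the 12, 0 passed over all genes tested with edgeR, 2 had an unadjusted p under 0.05, DESeq2 called 2 and voom 0, and 1 rose when adjusted over the list alone. The 29 mature neutrophil markers had a median of 0.04 (camera adjusted p 0.323), with 0.34 for Fpr1, 0.27 for Retnlg and -0.20 for Cd101. The 17 genes of neutrophil ageing and the CXCR4 axis had a median of 0.07 (adjusted p 0.972). Within that list Itgax, which encodes CD11c, had a log2 fold change of -0.74 with a standard error of 0.15 (16.3 ± 1.73 against 27.3 ± 5.50 CPM), Icam1 one of -0.51 and Itgam one of 0.33, and 1 gene fell when adjusted over the list alone. Over all genes tested 0 of the 17 passed with edgeR or voom, DESeq2 called 1 lower, and 1 was higher and 3 were lower at an unadjusted p under 0.05.

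Genes of the NADPH oxidase, which makes the neutrophil's reactive oxygen, and genes linked to polymorphonuclear myeloid-derived suppressor cells lay slightly higher in the Ly6C-high cells. All 8 oxidase genes had a log2 fold change above 0, with a median of 0.15, and 26 of 33 suppressor cell genes did, also with a median of 0.15. The values were 0.43 for Cybb, the catalytic subunit of the oxidase, and 0.31 for Ncf1, and for the suppressor cell genes 0.32 for Dgat2, 0.32 for Trem1 and -0.19 for Tgfb1. With edgeR 0 genes of either list passed over all genes tested or adjusted over the list alone, DESeq2 and voom also called 0, and 2 genes of each list had an unadjusted p under 0.05. The camera adjusted p was 0.0222 for the oxidase and 0.0199 for the suppressor cell list, and neither passed otherwise (adjusted p = 0.53 with an estimated correlation). The oxidase list rested on single libraries, with an adjusted p of 0.0756 without Ly6C-high replicate 1, 0.0758 without Ly6C-high replicate 2 and 0.145 without Ly6C-low replicate 3 (median 0.09), in a range from 0.0113 to 0.145. The suppressor cell list had an adjusted p of 0.105 without Ly6C-high replicate 3 (median 0.06) and 0.0610 without Ly6C-low replicate 3, in a range from 0.00653 to 0.105.

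Genes of the cytosolic ribosome lay lower in the Ly6C-high cells, with 78 of 79 log2 fold changes below 0, a median of -0.25 and quartiles of -0.33 and -0.20. Rpl22 measured 28.2 ± 3.05 CPM in the Ly6C-high and 38.0 ± 2.06 CPM in the Ly6C-low libraries, a log2 fold change of -0.43 with a standard error of 0.11, and the values were -0.37 for Rpl41 and -0.41 for Rpl13a. Ribosomal protein genes have many processed pseudogenes, so the count of any single member is uncertain. Adjusted over all genes tested, 0 of the 79 passed with edgeR, DESeq2 or voom, and 45 had an unadjusted p under 0.05, while 27 fell when adjusted over the list alone. The camera adjusted p was 7.69e-16, and the call was lost otherwise (adjusted p = 0.53 with an estimated correlation). The mean deviation of the list was 0.26 in Ly6C-low replicate 3, the highest of the 6 libraries, and the adjusted p stayed at 3.63e-10 or less when any 1 library was left out. The median was -0.17 once the trend with gene length was removed.

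Cell cycle, oxidative phosphorylation and unfolded protein response genes lay lower in the Ly6C-high cells as lists, but each of these calls depended on single libraries. The median log2 fold change was -0.27 over 38 cell cycle genes, -0.09 over 73 genes of oxidative phosphorylation and -0.13 over 31 genes of the unfolded protein response and secretory pathway, and 32, 61 and 25 of these genes lay below 0. Mcm7 and Gins2, which act in DNA replication, had log2 fold changes of -0.74 and -0.74, and Cenpe, a kinetochore motor, one of -0.87. The values were -0.49 for Ndufs3, -0.25 for Atp5l and -0.28 for Ndufa7 among the respiratory chain and ATP synthase genes, and -0.19 for Ern1, -0.18 for Hspa5 and -0.37 for Pdia4 among those of the unfolded protein response. With edgeR 0 members of the 3 lists passed over all genes tested or adjusted over the list alone, and DESeq2 and voom called 0. At an unadjusted p under 0.05 there were 3, 4 and 0 members. The camera adjusted p was 0.00124, 0.00213 and 0.0361 for the 3 lists, and all 3 calls were lost otherwise (adjusted p = 0.53 with an estimated correlation). Ly6C-low replicate 3 had a mean deviation of 0.46 in the cell cycle list, where the other libraries lay between -0.20 and 0.07. Without it the median of that list was -0.08 and the adjusted p 0.187, in a range from 5.59e-07 to 0.187, and without Ly6C-low replicate 1 the median was -0.41. The oxidative phosphorylation list had an adjusted p of 0.177 without Ly6C-high replicate 3 (median -0.05), in a range from 0.000188 to 0.177, and one of 0.686 with a median of -0.01 once the trend with gene length was removed. The unfolded protein response list had an adjusted p of 0.0758 and 0.177 without Ly6C-high replicates 2 and 3 (median -0.08 without the latter), and 0.0889 and 0.0745 without Ly6C-low replicates 1 and 2, in a range from 0.00486 to 0.177.

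**Figure D3:**
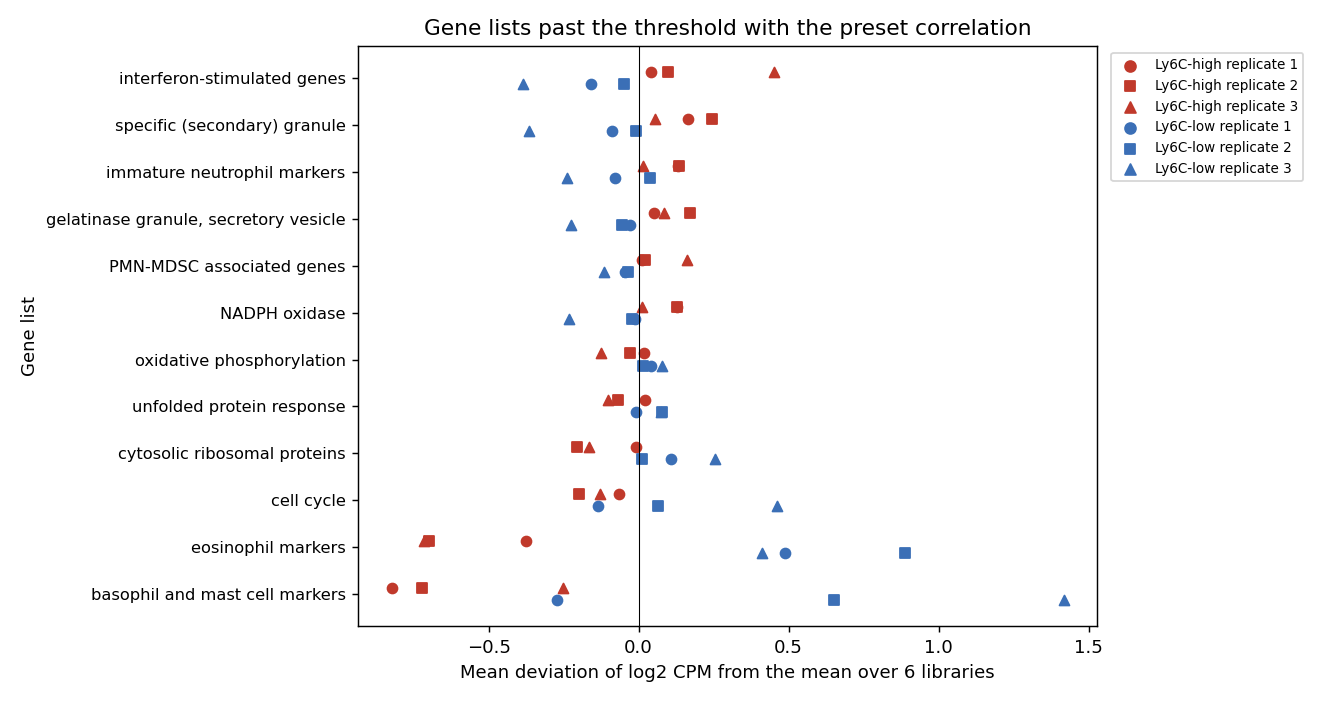
Each point is the mean deviation of log2 CPM of a gene list from its mean over the 6 libraries (horizontal axis), in 1 library (red, Ly6C-high; blue, Ly6C-low; symbols, replicates), for the 12 lists past the camera threshold with the preset correlation. Ly6C-low replicate 3 reaches -0.39 for interferon-stimulated genes and 1.42 for basophil and mast cell markers, and the 12 calls were not kept with an estimated correlation.

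The inflammatory, stress, antigen presentation and metabolic lists did not pass the camera test with group as the only term. The 33 cytokine, chemokine and NF-kB target genes had a median of 0.00 (adjusted p 0.815), with -1.09 for Ccl3 (-0.49 without Ly6C-low replicate 3), 0.50 for Tnf and -0.51 for Icam1. The 26 immediate early and stress genes had a median of -0.19 (adjusted p 0.112), with -0.31 for Jun, -0.16 for Jund and -0.77 for Dusp2 (-0.07 without Ly6C-low replicate 3). The median of that list was -0.06 and -0.34 without Ly6C-high replicates 1 and 3, and -0.33 and -0.09 without Ly6C-low replicates 1 and 3. Its mean deviation was -0.47, -0.04 and 0.18 in Ly6C-high and -0.25, 0.17 and 0.42 in Ly6C-low replicates 1, 2 and 3. It was thus lower in the Ly6C-high library of each number. With the replicate number as a block the list passed camera with the preset correlation (adjusted p 0.000492), but the labels do not say what the number marks. The 23 antioxidant genes had a median of 0.10 (adjusted p 0.176), with 0.25 for Txnrd1, 0.46 for Gclm and 0.31 for G6pdx, and the 22 glycolysis genes one of 0.09 (adjusted p 0.174), with 0.37 for Hk3, -0.39 for Pdk1 and 0.26 for Slc2a3. Class I antigen presentation had a median of -0.03 over 21 genes (adjusted p 0.317), with -0.36 for Erap1, -0.17 for H2-Q4 and -0.40 for Psmb10. Class II had a median of 0.17 over 11 genes (adjusted p 0.184), with 0.81 for H2-Eb1, 0.53 for H2-Aa and -0.23 for Ctss. With 1 library left out the class II median ranged from 0.14 to 0.40. Adhesion and chemotaxis receptors, which include Itgax, Fpr1 and Icam1, had a median of 0.08 over 29 genes (adjusted p 0.242), with 1 that fell when adjusted over the list alone, and apoptosis regulators one of 0.11 over 25 genes (adjusted p 0.176). Among the apoptosis regulators, 2 rose and 3 fell when adjusted over the list alone: the values were -0.50 for Pmaip1, which encodes the death-promoting protein NOXA, and 0.32 and 0.39 for Cflar and Xiap, which encode caspase inhibitors. Over all genes tested 0 members of these 8 lists passed with edgeR or voom, and DESeq2 called 1 adhesion receptor higher and 1 lower. At an unadjusted p under 0.05 there were 4 higher and 5 lower among the adhesion receptors and 3 in each direction among the apoptosis regulators. The immediate early list passed with the statistics of DESeq2 (adjusted p 0.0349) and of voom (0.0361). Without Ly6C-high replicate 3 the adjusted p was 0.00715 for the immediate early list and 0.0470 for the antioxidant, glycolysis and class II lists. It was 0.00292 for the immediate early and 0.0333 for the antioxidant list without Ly6C-low replicate 1, and 0.0322 for the glycolysis list without Ly6C-low replicate 2. Over all alternatives with 1 library left out it ranged up to 0.920, 0.816, 0.940 and 0.468 for the immediate early, antioxidant, glycolysis and class II lists. With an estimated correlation and all 6 libraries the camera adjusted p of these lists was 0.722, 0.722, 0.767 and 0.53. The median and the mean log2 fold change differed in sign in the mature marker, ageing, cytokine and adhesion lists, as did the median (-0.10) and the camera direction of the platelet list.

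Among the markers of other cells that the Ly6G gate could hold, those of eosinophils and basophils lay higher in the Ly6C-low cells. Of 6 eosinophil genes tested, 5 had a log2 fold change below 0, with a median of -0.66 (-1.37 without the filter on low counts). Alox15 fell over all genes tested with edgeR, where DESeq2 gave it no adjusted p and called 1 gene lower, Ccr3, and voom called 0. At an unadjusted p under 0.05 there were 4 lower, and 4 genes, Alox15, Ear1, Ccr3 and Siglecf, fell when adjusted over the list alone. Siglecf, an eosinophil lectin, measured 31.2 ± 5.88 CPM in the Ly6C-high and 43.7 ± 3.51 CPM in the Ly6C-low libraries, Ccr3, the eotaxin receptor, 7.18 ± 1.55 against 12.9 ± 0.722 CPM, and Ear1, a member of a family of near-identical ribonuclease genes, 0.105 ± 0.0549 against 1.72 ± 0.861 CPM. Ear1 passed over all genes tested without Ly6C-low replicate 3 (adjusted p 0.00886), with library size alone (0.0355) and among protein-coding genes (0.0402). With the replicate number as a block it also passed (0.005), as did Ccr3 (0.048) and Siglecf (0.0491). The camera adjusted p of the list was 0.000153, and the call was lost without the preset correlation (adjusted p = 0.53 with an estimated correlation). In fry's test for change in either direction its adjusted p was 0.0141, and in the test for change in 1 direction 0.0773. Of 9 basophil and mast cell genes 8 lay below 0, with a median of -1.73 and a camera adjusted p of 0.00327, which was also lost (adjusted p = 0.53 with an estimated correlation). Adjusted over all genes tested 0 of the 9 passed with edgeR, DESeq2 or voom, 3 had an unadjusted p under 0.05, and 3 fell when adjusted over the list alone: Mcpt8, Prss34 and Cpa3. Mcpt8, a basophil protease, measured 0.671 ± 0.136 against 4.78 ± 3.28 CPM, and passed over all genes tested without Ly6C-low replicate 1 (adjusted p 0.00779) or 3 (0.0304). With all 6 libraries Mcpt8 passed in edgeR with the replicate number as a block (0.005) and without the filter on low counts (1.52e-15). Without the filter single genes did not carry their own spread, so that last value ignores the wide spread of Mcpt8 in the Ly6C-low libraries. Hdc, the member that lay above 0, measured 1447 ± 155 against 1142 ± 241 CPM. Kit, the other abundant member, had a log2 fold change of -0.67 with a standard error of 0.35. It is also in the immature neutrophil list. The mean deviation of the basophil list was 1.42 in Ly6C-low replicate 3, and both lists kept their call without that library, but the basophil median was then -1.01. The groups overlapped in that mean, at -0.27 in Ly6C-low replicate 1 and -0.25 in Ly6C-high replicate 3.

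The other marker lists did not pass the camera test with group as the only term. The 19 monocyte and macrophage genes had a median of 0.08 (adjusted p 0.216), but a mean of 0.36 and an upper quartile of 0.74. The 2 most abundant, Mpeg1 and Csf1r, had log2 fold changes of -0.35 and -0.18. Summed over the list, the level was 1046, 977.3 and 979.9 CPM in Ly6C-high and 1237, 1127 and 1135 CPM in Ly6C-low replicates 1, 2 and 3. Most of that sum came from Mpeg1 (398 against 506 CPM) and Csf1r (342 against 388 CPM). The mean deviation, which weighs each gene alike, pointed the other way. It was 0.13, 0.34 and -0.03 in Ly6C-high and -0.11, -0.03 and -0.31 in Ly6C-low replicates 1, 2 and 3. Whether monocytes lay in the Ly6C-high gate was not tested. Adjusted over the list alone 4 monocyte genes rose and 1 fell: Ccr2, the chemokine receptor of classical monocytes, measured 11.2 ± 0.769 against 6.96 ± 2.22 CPM. Over all genes tested 0 monocyte genes passed with edgeR, DESeq2 or voom, and 5 were higher and 2 lower at an unadjusted p under 0.05. T cell genes had a median of 0.12 over 5 genes (adjusted p 0.174; Cd3d 0.41), B cell genes 0.10 over 11 (0.696; Ighm -0.09, Bank1 0.38), and NK cell genes 0.18 over 4 (0.653; Il2rb 0.67, Gzma 0.87). Platelet genes had a median of -0.10 over 13 genes (adjusted p 0.972), with F2rl2 at 0.48 and Itgb3 at 0.34, and erythroid genes one of -0.19 over 9 (adjusted p 0.286), with Hbb-bs at -0.21 and Hba-a2 at -0.19 (0.16 and 0.19 without Ly6C-high replicate 3). The 4 carcinoma and epithelial genes tested, which 4T1 cells could bring, had a median of -0.42 (adjusted p 0.176), and Cdh1 and Muc1 measured 10.4 ± 4.55 against 16.3 ± 6.23 and 2.62 ± 0.445 against 2.98 ± 0.466 CPM. Of the dendritic cell genes 3 were tested, too few for a list test, with Tcf4 at 0.25 and Bst2 at 0.06. Without Ly6C-high replicate 3 the monocyte, T cell and erythroid lists each had an adjusted p of 0.0470, and the median of the erythroid list was then 0.22, on the other side of 0. That library held 273.7 CPM of erythroid transcripts, where the other 5 held between 616.2 and 935.5. Single libraries also turned the sign of other medians: that of the monocyte list was -0.13 without Ly6C-low replicate 3, and that of the T cell list -0.08 without Ly6C-low replicate 1. The B cell median lay below 0 without Ly6C-high replicate 1 or 2 or Ly6C-low replicate 1 (-0.14 at the lowest). The platelet median lay above 0 without Ly6C-high replicate 1 or 3 or Ly6C-low replicate 1 or 2 (0.26 at the highest). With 1 library left out the carcinoma median ranged from -0.60 to -0.11, the latter without Ly6C-low replicate 1, and was -0.25 without Ly6C-high replicate 2, and the NK cell median ranged from 0.07 to 0.87.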

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

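Transcripts whose identifiers the annotation did not hold were outside every comparison, and on average 0.244% of the estimated counts of a library lay on them, which is above 0. The share was between 0.233% and 0.253% in each of the 6 libraries. No biological explanation was tested.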

How the results depend on the processing

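The trend corrections for gene length and GC content were chosen after the data were seen, and all other alternatives before. Every one of the 4 called genes kept its direction under each alternative that gave it a value, as did the 12 called lists. The 4 genes past the threshold, 2 higher, 2 lower and 3 of 2-fold or more, became 8 with library size alone (6 lower, 5 of 2-fold or more), where the 4 were kept. Without a filter there were 438 among 20580 genes (225 higher, 213 lower, 86 of 2-fold or more), which included the 4. The prior degrees of freedom, 7.51 at the median with the filter, were then infinite, so single genes no longer carried their own spread. DESeq2 gave 92 (56 higher, 36 lower, 7 of 2-fold or more), which included 3 of the 4 and gave Alox15 no adjusted p. The cause of that larger count was not tested. voom gave 3 genes (3 higher, 0 lower), 2 of them shared, and length-scaled TPM gave 2 (2 higher, 0 lower). Alox15 and Fam49a had adjusted p values of 0.0878 and 0.0756 with voom and 0.119 and 0.0647 with length-scaled TPM, and the cause was not tested. With 1 library left out, the count lay between 2 and 22, with 2 to 6 higher, 0 to 16 lower and 2 to 9 of 2-fold or more. The count of lists lay between 9 and 16, and 9 was reached without Ly6C-low replicate 3. The highest gene counts were all without Ly6C-low replicate 3, where 2 of the 4 genes were shared, and the cause was not tested.

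The number of lists was 0 with an estimated correlation and 0 with fry for change in 1 direction, against 12 with the preset correlation. In fry's test for change in either direction the eosinophil list alone passed (0.0141). Beyond the losses given with each list, DESeq2 ended the calls of the cell cycle (adjusted p 0.117, median -0.15), suppressor cell (0.0766) and unfolded protein response lists (0.0501). The last was also lost with a mean count filter (0.0503), length-scaled TPM (0.0673) and the length trend removed (0.0763), and the oxidase list with library size alone (0.0610). The median of the erythroid list lay between -0.47 and 0.22 with 1 library left out and was 0.22, with an adjusted p of 0.0470, without Ly6C-high replicate 3, and the cause was not tested. Library size alone moved the medians to 0.11 for the gelatinase granule, 0.18 for the immature, 0.04 for the oxidase and suppressor cell, -0.20 for the oxidative phosphorylation and -0.24 for the unfolded protein response list. The medians of the mature marker, cytokine and antioxidant lists lay on the other side of 0 with some single library left out. Among genes below the threshold, H2-Aa was 0.18 and H2-Eb1 0.36 without Ly6C-high replicate 2, F2rl2 0.08 without Ly6C-low replicate 3 and Kit -0.33 without Ly6C-low replicate 1. Without Ly6C-low replicate 3 Dgat2 was 0.17, G6pdx 0.16, Gclm 0.29, Hk3 0.23, Hdc 0.18, Lyz2 0.37 and Gins2 -0.48, Trem1 was 0.18 without Ly6C-high replicate 3, and Gzma lay between 0.48 and 1.34 with 1 library left out. These are examples, and other named genes moved as much. Without a filter the T cell (adjusted p 0.00125), class II (0.0395) and natural killer lists (0.0485) passed, as did the glycolysis list with the GC trend removed (0.0439). In the simulation over all 11406 genes, with 200 changed per run and every gene drawn independently, a 1.5-fold change was called in 34.48% of cases. The share is lower where fewer genes pass.

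The labels give both groups the replicate numbers 1 to 3 without saying that a number marks a mouse or a day. With the replicate number as a block, 61 genes passed (33 higher, 28 lower, 15 of 2-fold or more), the 4 and Lars2 (adjusted p 1.6e-06) among them. Members of the lists among them included Mmp8 (0.0367), Ceacam10 (0.0491), Ifit2 (0.0375), Itgax (0.0168) and Egr1 (0.00932), which did not pass with group as the only term. With the block 14 lists passed, which added the immediate early (0.000492) and the 4T1 carcinoma lists (0.0496). The block lowered the common biological coefficient of variation from 13.7% to 11.1%. The deviations from the group means of same-numbered libraries correlated at 0.237, -0.037 and 0.239 across all genes, so the numbers were not taken as pairs. Over genes with a log2 CPM above 3 the values were 0.335, 0.089 and 0.273, and there each library correlated best with its own number in the other group, a hint from the data and not from the design.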

Other observations

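The 7 genes of this paragraph lie outside the gene lists and were chosen after their values were seen. They did not pass with edgeR with all 6 libraries, the filter and scaling of the report and group as the only term. Nt5e, which encodes CD73, the ecto-enzyme that makes adenosine, measured 17.1 ± 0.699 CPM in the Ly6C-high and 7.51 ± 2.47 CPM in the Ly6C-low libraries (SD, n = 3 each), a log2 fold change of 1.18 with an adjusted p of 0.142. Mcam, the adhesion molecule CD146, had a log2 fold change of 0.60 (adjusted p 0.120), Cd55, a brake on complement, one of 0.59 (0.172), and Clec5a, a receptor of myeloid cells, one of 0.48 (0.142). Lower in the Ly6C-high cells were Ninj1, which acts in plasma membrane rupture, at -0.71 (0.142), Gm2a, a lysosomal lipid-transfer protein, at -0.56 (0.142), and the sterol transporter gene Abcg1 at -0.48 (0.142). Without Ly6C-low replicate 3 edgeR called Nt5e (adjusted p 0.00978), Gm2a and Abcg1 (0.0194 each), and with library size alone Gm2a and Abcg1 (0.0272 each). With the replicate number as a block it called Nt5e and Mcam (0.0168 each), Gm2a (0.0234), Clec5a (0.0375) and Abcg1 (0.0448). All 7 were called with edgeR without the filter and with DESeq2, which is no separate evidence, since they were chosen from the same libraries.

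The most abundant neutrophil transcripts differed by small amounts. The genes of this paragraph lie outside the rule for named genes. S100a9 measured 53730 ± 1760 against 46580 ± 3870 CPM and S100a8 36450 ± 1190 against 33160 ± 725 CPM, with log2 fold changes of 0.21 and 0.14 and 95% intervals from -0.05 to 0.47 and from -0.10 to 0.38. For both genes all 3 Ly6C-high libraries lay above all 3 Ly6C-low libraries. The chemokine receptor gene Cxcr2 had an interval from -0.10 to 0.39, Csf3r, the receptor for G-CSF, one from -0.42 to 0.09, and Arg2 one from -0.16 to 0.24, so changes of 1.5-fold in these genes lie outside their intervals. Il1b, at 3121 ± 771 against 3381 ± 744 CPM, had a wider interval from -0.59 to 0.36.

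Of the tests below, the second eosinophil and basophil list and the ribosomal RNA rank were set before their results were seen, and those on a single library, on gene length, on GC content and on other splits were chosen after the results were seen. Eosinophil and basophil genes were higher in the Ly6C-low cells, and a candidate explanation is that a few eosinophils or basophils, which a Ly6G gate should largely remove, lay in the Ly6C-low gate. Without Ly6C-low replicate 3 the eosinophil list had a camera adjusted p of 7.34e-06 with the preset correlation (0.00213 or less with any 1 library left out). With an estimated correlation and all 6 libraries it was 0.53. The eosinophil median lay between -0.97 and -0.66 with 1 library left out, so it did not rest on that library alone. The basophil median moved from -1.73 to -1.01 without that library, which therefore carried part of the basophil difference. A second list of 16 eosinophil and basophil genes had 4 tested members, Slc18a2, Hgf, Il1rl1 and Adgre1, with a median log2 fold change of -0.165 and a camera p of 0.977, too few and too mixed to decide. Of the 11 eosinophil genes 3 and of the 11 basophil genes 1 are also in another list, and the most abundant members, Siglecf at 43.7 and Hdc at 1142 CPM in the Ly6C-low cells, were also present in the Ly6C-high cells at 31.2 and 1447 CPM. Other cells in the gate and a difference in the neutrophils themselves, which was not tested, therefore cannot be told apart.

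Interferon-stimulated genes were higher and ribosomal protein genes lower in the Ly6C-high cells, and across genes the log2 fold change followed gene length (Spearman 0.158) and GC content (-0.189), though genes are not independent replicates. With the length trend removed the larger camera adjusted p of both lists was 1.17e-10 (medians 0.40 and -0.17, from 0.42 and -0.25). With the GC trend removed it was 8.04e-12 (0.40 and -0.22), and without Ly6C-low replicate 3 it was 2.44e-10 (interferon median 0.27). These p-values used the preset correlation, which also passed up to 15 lists in other splits of the libraries, so they cannot exclude these explanations. Both medians kept their sign in each setting, so part of the difference remained. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split gave 12 lists, and the highest of the other splits gave 15, with 3 splits at 12 or more, the real one included. Those list calls used the preset correlation, and with an estimated correlation both lists had an adjusted p of 0.53, and a difference in interferon exposure or in translation between the cells remains a hypothesis, which was not tested here.

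The count of called genes met the same limit of 10 splits. The real split gave 4 genes and the highest other split 0, and for changes of 2-fold or more the counts were 3 and 0. So 1 split of 10, the real one, gave as many in each case. Ly6c1 and Ly6c2 are in both counts, and the cells were sorted on Ly6C, so their call in the real split was set by the sort. At an unadjusted p under 0.05 the real split gave 1626 and the highest other 949. Without the filter the real split gave 438 and the highest other 106, and with DESeq2 92 and 17.

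Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, varied 12.8-fold between the libraries, at 6953, 2510 and 6736 CPM in Ly6C-high replicates 1, 2 and 3 and 1943, 541 and 1814 CPM in Ly6C-low replicates 1, 2 and 3 (log2 fold change 1.91, adjusted p 0.340), so that all 3 Ly6C-high libraries lay above all 3 Ly6C-low libraries. At least 99.873% of its estimated counts in each library lay on 1 of its 9 transcripts, and a candidate explanation is that ribosomal RNA reads were assigned to it. The annotated ribosomal RNA gene CT010467.1 had rank 1 of all genes tested by its correlation with Lars2 (Pearson r 0.996, exact permutation p 0.00556; Spearman rho 0.886, exact permutation p 0.0333; n = 6 libraries; r 0.985 without the 2 farthest libraries). The groups hold too few libraries to test the relation within each. The relation leaves open, as a hypothesis from these 6 libraries, that ribosomal RNA reads may add to the Lars2 level. A difference in Lars2 itself was not tested. CT010467.1 was also higher in all 3 Ly6C-high libraries, at 453, 178 and 462 against 154, 57.8 and 169 CPM in replicates 1, 2 and 3. With the replicate number as a block edgeR called Lars2 (log2 fold change 1.98, adjusted p 1.6e-06) and CT010467.1 (1.54, 3.05e-06). Whether the share of ribosomal RNA reads differed between the groups for technical reasons was not tested.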
